A study of Homo sapiens with 20 samples.

How the data were processed

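HK2, an immortalized human proximal tubule cell line, was grown as 5 conditions: untreated cells (Control), cells given the solvent dimethyl sulfoxide (DMSO), and cells given 500 µM hydrogen peroxide (H2O2), 8 ng/ml TGF-B1 or 50 µM FG4592 for 48 h. FG4592 (roxadustat) is an inhibitor of the prolyl hydroxylases that mark hypoxia-inducible factor (HIF) for degradation, and DMSO is its solvent control. Each condition had 2 ATAC-seq samples, which measure open chromatin with the Tn5 transposase, and 2 RNA-seq samples, 20 samples in all. The labels number replicates within a condition but do not say whether they came from separate cultures, so p-values measure the spread between these samples, which may be technical.

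The submitters' processing notes name cutadapt, Bowtie2, SAMtools, Picard and MACS2 as well as kallisto and sleuth, with no versions, and the builds hg19 and GRCh37. kallisto estimates transcript abundance without genome alignment and sleuth tests it. The settings of each step, the annotation release and the handling of Tn5 cut positions are not given in the sources used here.

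The authors deposited 1 gene table per comparison, H2O2 against Control, TGF-B1 against Control, FG4592 against DMSO and FG4592 against Control. The deposited expression values are a normalized signal. The file names call them TPM, an abundance unit that adds up to the same sum in every library, but library sums run from 943098 to 1060726, and a library that stands in 2 tables differs between them by 1 constant ratio, for example 1.045 for Control library 01. They were therefore treated as TPM divided by a size factor per library and table, and are called normalized TPM. The planned test, written for TPM, was kept. Each table also gives the authors' deposited p-value, q-value and log2 fold change per gene, and the sleuth model behind them is not described in the file headers. The deposited log2 fold changes equal the log2 ratio of the group means. The tables hold no read counts per sample, so the depth of each library is unknown and no counting interval is given.

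Library columns carry a number from 01 to 12 and a letter, and the letter was matched to the condition. The number does not match the replicate number in the labels, so libraries are named by their column number and none was paired with another in the reported fits. Rows that share a gene symbol, mostly copies of 1 gene on alternative haplotypes, were summed. Such symbols held from 6.61% to 6.88% of the signal.

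Genes were tested within each table with limma 3.58.1 in R 4.3.3. The test was two-sided, moderated with a mean-variance trend, and used log2(value + 1), 2 libraries against 2. Genes with a mean of at least 1 normalized TPM were kept, between 14018 and 14187 per table, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. Every adjusted p for a gene below comes from this fit, and fold changes are on the log2(value + 1) scale, which understates changes of low genes. On data simulated from each table's mean values and fitted variances, 4-fold changes were called in 98% of changed genes for the H2O2 table, 91% for TGF-B1, 90% for FG4592 against DMSO and 96% for FG4592 against Control. For 2-fold changes these shares were 33%, 32%, 28% and 27%, so a gene that was not called may have changed by that much. The simulation held 100 changed genes per size, far fewer than were called with FG4592 (2782 against DMSO and 2492 against Control). The adjustment is stricter where fewer genes change. These shares may therefore understate how often such changes were called in the FG4592 comparisons. Between 5 and 7 unchanged genes were called per table.

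Gene lists, 33 in number, were fixed before the data were examined. Lists with at least 5 tested members were tested against all other genes with camera (limma) at a preset correlation of 0.01, adjusted over lists, and again with an estimated correlation. No list call in any of the 4 comparisons held with the estimated correlation, which 4 libraries determine poorly. Named genes were fixed by rule at the same time. They are the 10 largest rises and 10 largest falls per comparison among called genes with a mean of at least 5 and no overlap between groups, without clone-based names and pseudogenes, the 4 members with the smallest p of each called or treatment-related list, and 12 genes taken in every comparison. Some of these genes are not reported here and not counted among named genes under the alternatives. Near-identical family members, such as the CGB genes, HSPA1A and HSPA1B, the metallothioneins and nuclear copies of mitochondrial genes, share reads, and the division between them is uncertain.

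Differential ATAC-seq regions were deposited as 0-based intervals on hg19 without score, fold or direction. They could be counted and compared but not retested, and whether peaks were called on single or pooled samples is not stated. In every list the chromosome order starts over once, which divides the list into 2 runs. What the runs stand for is not stated, so they are called run 1 and run 2 and given no direction. The order of the runs is not the same in every file, since the FG4592 file of both comparisons has the runs of the Control list in the other order (2343 and 2080 regions), and equal run numbers in 2 files are not taken to mean the same. Overlap was computed with bedtools 2.31.1 at 1 bp or more, with at least 0.5 of the shorter region, and within 1 kb. Gene neighbourhoods and sequence motifs of the regions need an hg19 genome and annotation and were not analysed here.

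Alternatives were another pseudocount (0.1 or 5), no filter or a filter at 5, a shift to equal library medians, the authors' q-values, and each library left out in turn. Chosen after seeing the data were library sums set equal, the number series of the columns (01 to 06 against 07 to 12) as a covariate, rows left unsummed, and 1 fit over all 10 RNA-seq libraries on a common scale. That scale was built from genes present in every table with median-of-ratios factors, and comparisons between groups of different tables rest on it alone. In each treatment comparison the number series left 1 residual degree of freedom, so p-values of that fit lean heavily on variances borrowed from other genes. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 was used for tables and matplotlib 3.10.9 for plots.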

Results

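Gene expression and open chromatin were profiled in HK2 cells, a line of human proximal tubule epithelium, under 5 conditions with 2 RNA-seq and 2 ATAC-seq samples each. The series asks how tubular cells respond to outside stimuli. Control cells were the reference for hydrogen peroxide and TGF-B1, and both DMSO-treated and Control cells for FG4592. RNA-seq values are normalized TPM per gene, and each comparison was made within its own table. The depth of the libraries is unknown, because no read counts per sample are in the tables. Between 13771 and 14144 genes per library reached 1 normalized TPM.

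The H2O2 comparison asks which transcripts differ after oxidant exposure. Most tested genes of the integrated stress response, which cells use when amino acids or protein folding fail, rose with H2O2. SLC7A5, an amino acid transporter, rose from 15.5 ± 3.49 to 73.3 ± 14.8 normalized TPM (SD, n = 2, log2 fold change 2.18 ± 0.22 SE, adjusted p = 0.0161). The authors' deposited q for SLC7A5 was 0.117. ASNS, which makes asparagine, rose by 2.60 on the log2 scale (adjusted p = 0.00746), the cystine transporter gene SLC7A11 by 2.14 and the glycyl-tRNA synthetase gene GARS by 1.25. Of 32 tested list members 20 rose and 1, VLDLR, fell (log2 fold change -1.48), a gene named after its value was seen. Adjusted over the list alone, 29 rose. The list median was 1.22 (camera adjusted p = 6.84e-25, adjusted p = 0.602 with an estimated correlation).

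Most mitochondrially encoded transcripts fell with H2O2. MT-CO1, a subunit of cytochrome c oxidase, went from 19767 ± 177 to 3019 ± 868 normalized TPM (log2 fold change -2.74 ± 0.25 SE, adjusted p = 0.0161), and MT-CO2 and MT-CYB had log2 fold changes of -2.38 and -1.84. The list of 13 had 8 members that fell and none that rose, with 11 lower when adjusted over the list alone and a median of -1.73 (camera adjusted p = 4.17e-11, adjusted p = 0.629 with an estimated correlation). As a share of all signal, mitochondrial genes made up 10.3% and 9.87% in the Control libraries and 2.45% and 4.49% in the H2O2 libraries. Nuclear-coded subunits of oxidative phosphorylation had no called member among 33 and a median of 0.09 (camera adjusted p = 0.129).

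Targets of NRF2, the transcription factor that answers electrophiles and oxidants, had 5 of 29 members higher and 0 lower (camera adjusted p = 2.68e-05, adjusted p = 0.602 with an estimated correlation). NQO1, a quinone reductase, rose from 131 ± 12.3 to 356 ± 17.4 normalized TPM, and TXNRD1, thioredoxin reductase, from 199 ± 4.97 to 458 ± 43.2. FTH1, the ferritin heavy chain, rose by 1.31 on the log2 scale. HMOX1, heme oxygenase, had 21.5 ± 0.758 in Control and 37.6 ± 13.8 with H2O2, which did not pass the test (adjusted p = 0.194). Among 30 other antioxidant enzymes 0 rose and 1, the metallothionein gene MT1F, fell (camera adjusted p = 0.0126, adjusted p = 0.602 with an estimated correlation).

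Among the largest rises were those of G0S2, an inhibitor of fat breakdown that went from 44.5 ± 1.55 to 355 ± 70.0 normalized TPM, GFPT2 of the hexosamine pathway (log2 fold change 2.91), INHBE, an activin subunit (2.64), and the glycine transporter SLC6A9 (2.62). ANGPTL4, SCG5, DUSP5 and the stress cytokine GDF15 rose by between 2.29 and 2.50. Besides mitochondrial genes, the largest falls were those of FGB, the fibrinogen beta chain, from 133 ± 27.9 to 12.2 ± 6.66 normalized TPM (log2 fold change -3.43 ± 0.34 SE, adjusted p = 0.0161), FXYD2, a regulator of the sodium pump (-2.82), SPNS2 (-2.51), LTB and VAV3 (both -2.48), UNC5CL (-2.41), the tubular injury marker HAVCR1 (-2.30) and FGFR2 (-2.26).

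Inflammatory NF-kappaB genes had 3 of 26 members higher, IL8, IL11 and TNFAIP3, and 1 lower, TNFAIP2 (camera adjusted p = 0.00123, adjusted p = 0.602 with an estimated correlation). In the AP-1 family FOSL1 and ATF3 rose, 2 of 16 (camera adjusted p = 0.0263, adjusted p = 0.629 with an estimated correlation). Extracellular matrix genes went both ways, with LAMB3 and TNC higher and 3 of 37 lower, LAMA5 and COL4A1 among them (camera adjusted p = 0.025, adjusted p = 0.777 with an estimated correlation). Of the TEAD and YAP list NT5E and ANKRD1 rose while IGFBP3 and TGFB2 fell. The list as a whole lay lower, with a median of -0.37 and 3 of 27 members above 0 (camera adjusted p = 0.000101, adjusted p = 0.629 with an estimated correlation). Adjusted over the list alone, 2 rose and 6 fell. Glycolysis genes had 0 called members of 20, and 9 lower adjusted over the list alone, with a median of -0.43 (camera adjusted p = 7.34e-05, adjusted p = 0.629 with an estimated correlation). Cholesterol synthesis had 0 called of 25 and a median of -0.76 (camera adjusted p = 7.61e-06, adjusted p = 0.751 with an estimated correlation). Histone genes had 0 called of 8 and a median of -0.54 (camera adjusted p = 0.0126, adjusted p = 0.629 with an estimated correlation), and ribosomal protein genes 0 of 50 and 0.21 (camera adjusted p = 3.46e-05, adjusted p = 0.777 with an estimated correlation). With the number series of the libraries as a covariate, 18 cholesterol synthesis, 9 glycolysis and 1 of the histone genes were called lower and 3 ribosomal protein genes higher. VEGFA stood at 64.0 ± 27.3 and 293 ± 157 normalized TPM (adjusted p = 0.0533) and CA9 at 21.2 ± 14.3 and 4.09 ± 1.00 (adjusted p = 0.077). Both were called with the number series as a covariate (adjusted p = 0.000944 and 0.0227).

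In all, 256 of 14187 genes were called with H2O2, 117 higher and 139 lower, and 2634 had an unadjusted p below 0.05. With library sums set equal, 58.1% of calls were higher instead of 45.7%. The count was 85 with no filter, 182 without H2O2 library 02 (67 higher, 115 lower), 556 without Control library 01 (301 higher, 255 lower), 580 without Control library 07, 696 without H2O2 library 08 and 1181 with the number series as a covariate, a setting chosen after the data were seen. In the last of these fits 27 integrated stress response genes were higher and 1 lower, 11 NRF2 targets, 9 NF-kappaB and 6 AP-1 genes higher, 2 NF-kappaB genes, 11 mitochondrial transcripts and 6 other antioxidant enzymes lower, 4 extracellular matrix genes higher and 13 lower, and 2 TEAD and YAP genes higher and 6 lower. Of 43 called genes named by rule 35 stayed called with any 1 library left out, and 8 of 12 called lists did. Without H2O2 library 02 ANKRD1, ATF3, COL4A1, NT5E, TGFB2, TNC, TNFAIP2 and TNFAIP3 were not called, ANKRD1 and TNFAIP3 also without H2O2 library 08, and TNFAIP3 without Control library 07. The lists not called were the AP-1 family without H2O2 library 02 or Control library 07, and extracellular matrix, histones and other antioxidant enzymes without Control library 01. With no filter ANGPTL4, FTH1, GDF15, IL8, LAMA5, LTB, MT-CO2, MT-CYB, MT1F, SCG5 and SPNS2 were among the genes not called, and on the common scale ANKRD1, ATF3, IGFBP3, LTB, MT1F, NT5E and SCG5.

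**Figure D1:**
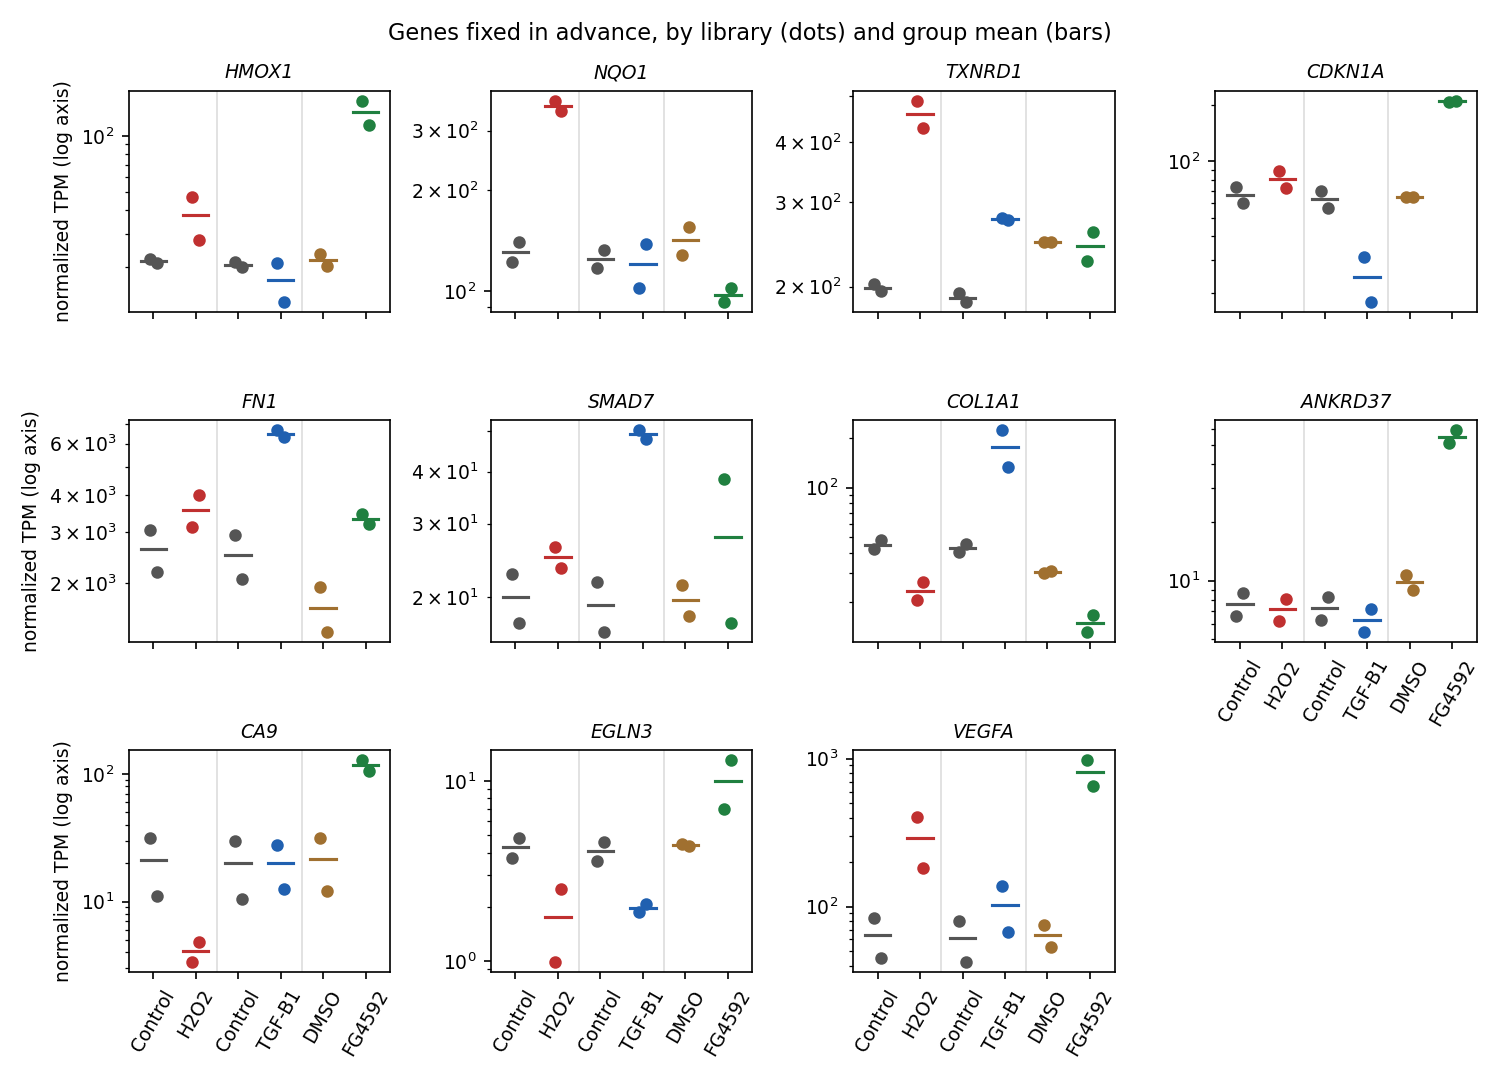
Normalized TPM (log axis) of genes fixed before the data were examined, with 1 dot per library and a bar at each group mean, for H2O2 and TGF-B1 beside Control and for FG4592 beside DMSO. NQO1 and TXNRD1 stand higher with H2O2, FN1, SMAD7 and COL1A1 with TGF-B1, and ANKRD37, CA9, VEGFA, HMOX1, CDKN1A and FN1 with FG4592.

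TGF-B1, a cytokine that drives fibrosis, was compared with the same Control libraries. Part of its known target genes rose. IL11, a cytokine induced in fibrosis, went from 50.3 ± 0.764 to 409 ± 95.5 normalized TPM (SD, n = 2, log2 fold change 2.98 ± 0.18 SE, adjusted p = 0.0086). JUNB, LTBP2 and BHLHE40 rose by 1.72, 1.75 and 1.36 on the log2 scale, and the feedback inhibitor SMAD7 by 1.33. Of 37 tested targets 17 rose and 0 fell, and 28 rose adjusted over the list alone. The median was 1.05 (camera adjusted p = 2.04e-23, adjusted p = 0.429 with an estimated correlation).

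Matrix and mesenchymal genes rose in part. COL1A1, the main chain of collagen I, went from 42.8 ± 3.40 to 178 ± 64.0 normalized TPM (log2 fold change 1.99 ± 0.25 SE, adjusted p = 0.021), and COL3A1, FN1 and TNC rose by 1.98, 1.40 and 1.26 on the log2 scale. Extracellular matrix genes had 8 of 38 members higher and 2 lower (camera adjusted p = 1.47e-05, adjusted p = 0.631 with an estimated correlation). Among 16 mesenchymal markers 5 rose and 0 fell, with SNAI1, a repressor of epithelial genes, at 1.63, TAGLN at 1.54 and N-cadherin, CDH2, at 0.90 (camera adjusted p = 1.47e-05, adjusted p = 0.429 with an estimated correlation). COL1A1 and COL3A1 are also the 2 called members of the 5 tested fibroblast markers (camera adjusted p = 0.00196, adjusted p = 0.429 with an estimated correlation), while PDGFRB and LUM did not pass the test. With the number series as a covariate PDGFRB was called (adjusted p = 0.0361). Endothelial, leukocyte and distal tubule lists had 1 or 2 tested members each.

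Epithelial markers had 3 of 21 members lower, ELF3 (log2 fold change -1.97), EPCAM (-1.65) and KRT19 (-1.40), and 1 higher, the desmosome gene DSP (1.33) (camera adjusted p = 0.0113, adjusted p = 0.429 with an estimated correlation). Proximal tubule markers had 0 called of 14 and a median of -0.47 (camera adjusted p = 0.0118, adjusted p = 0.634 with an estimated correlation), or 7 lower with the number series as a covariate. Tubular injury markers had 6 of 19 lower and 0 higher (camera adjusted p = 0.00391, adjusted p = 0.631 with an estimated correlation). DCDC2 went from 51.8 ± 8.90 to 7.94 ± 0.672 normalized TPM, GDF15 from 37.0 ± 7.76 to 6.93 ± 3.22, and VCAM1, an adhesion molecule, and HAVCR1, the injury marker KIM-1, had log2 fold changes of -2.27 and -1.76. The interferon list, with 27 tested members, had a median of -0.52 (camera adjusted p = 2.32e-07, adjusted p = 0.429 with an estimated correlation).

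Other antioxidant enzymes had SOD2 and MGST1 lower and PRDX1 higher among 30 (camera adjusted p = 0.00888, adjusted p = 0.429 with an estimated correlation). JUNB and FOS rose among 16 AP-1 genes (camera adjusted p = 0.0129, adjusted p = 0.688 with an estimated correlation). FOS also stood higher in DMSO than in Control on the common scale (log2 difference 2.672 ± 0.555 SE, limma adjusted p = 0.503). That difference was not called, but the rise of FOS may not be particular to TGF-B1. GDF15 was the 1 called member of 26 p53 targets in the reported fit (camera adjusted p = 0.0184, adjusted p = 0.688 with an estimated correlation), against 2 higher and 5 lower with the number series as a covariate. Lists with 0 called members that passed camera were apoptosis (27 tested, lower, adjusted p = 0.00976), the unfolded protein response (26, higher, 0.0189), mitosis (34, higher, 0.00391), histones (9, higher, 0.0113) and ribosomal proteins (50, higher, 0.0276). Their adjusted p with an estimated correlation was 0.605, 0.605, 0.864, 0.472 and 0.864. With the number series as a covariate apoptosis genes had 7 members lower and 2 higher, and 5, 4, 1 and 0 members were higher in the other lists in this order. Mitochondrial transcripts had 0 called of 13 and a median of -0.16 (camera adjusted p = 0.141). With the number series as a covariate 1 was called lower and the list passed camera (camera adjusted p = 0.00542, adjusted p = 0.695 with an estimated correlation). Their share of the signal was 9.24% and 8.35% in the TGF-B1 libraries.

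Among the largest rises with TGF-B1 were those of CGB5 and CGB8, genes of the chorionic gonadotropin beta chain, with log2 fold changes of 5.09 and 3.92. CGB8 went from 7.56 ± 0.793 to 130 ± 35.1 normalized TPM. CGB7 and CGB rose as well, and reads of this family cannot be divided with certainty. AMTN, amelotin, went from 0.341 ± 0.195 to 26.6 ± 3.88, and EGR1, an immediate-early factor, from 4.89 ± 1.94 to 78.2 ± 56.3. EGR1 also stood higher in DMSO than in Control on the common scale (log2 difference 3.363 ± 0.598 SE, limma adjusted p = 0.391). That difference was not called, but the rise of EGR1 may not be particular to TGF-B1. SCG5 and FAM198B rose by 3.03 and 2.92 on the log2 scale. Among the largest falls were those of FXYD2 (log2 fold change -3.08), HLA-DMB (-2.86), WFDC2 (-2.81), EPAS1, which encodes HIF-2 alpha (-2.65), CRISPLD2 (-2.64), SPNS3 (-2.63), TSPAN1 (-2.58) and FLRT3 (-2.52). EPAS1 went from 70.2 ± 5.65 to 10.5 ± 3.13 normalized TPM (adjusted p = 0.0114).

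With TGF-B1 374 of 14018 genes were called, 186 higher and 188 lower, and 2024 had an unadjusted p below 0.05. Between 301 and 373 were called with 1 library left out, with 219 higher and 121 lower without Control library 01 and 128 higher and 245 lower without TGF-B1 library 06. Fitted with the number series as a covariate, 839 were higher and 907 lower, 1746 in all, among them 28 TGF-beta targets, 10 mesenchymal markers, 4 AP-1 genes and 3 fibroblast markers higher, 18 extracellular matrix genes higher and 5 lower, 5 epithelial markers higher and 6 lower, 4 tubular injury markers higher and 8 lower, and 1 of the other antioxidant enzymes higher and 12 lower. Of 40 called genes named by rule 34 stayed called with any 1 library left out, and 9 of 16 called lists did. CDH2 and PRDX1 were not called without any 1 of the 4 libraries, MGST1 without Control library 01, Control library 07 or TGF-B1 library 06, FOS and SOD2 without Control library 01 or TGF-B1 library 06, and WFDC2 without Control library 01. FOS was not called with no filter, a filter at 5, a pseudocount of 5, a median shift or the common scale either. The lists not called were ribosomal proteins without Control library 07 or either TGF-B1 library, the unfolded protein response without Control library 01 or either TGF-B1 library, mitosis without Control library 01 or TGF-B1 library 12, histones and the AP-1 family without Control library 07 or TGF-B1 library 06, p53 targets without Control library 07, and proximal tubule markers without TGF-B1 library 12.

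FG4592 was set against its solvent, DMSO, to read the response to prolyl hydroxylase inhibition. HIF targets rose almost as a whole. ANGPTL4, an inhibitor of lipoprotein lipase, went from 3.54 ± 1.40 to 593 ± 85.5 normalized TPM (SD, n = 2, log2 fold change 7.06 ± 0.23 SE, adjusted p = 4.17e-05). VEGFA, the vascular growth factor, went from 64.5 ± 15.8 to 812 ± 231, the lipid droplet gene HILPDA from 26.0 ± 5.05 to 479 ± 11.1, and the carbonic anhydrase gene CA12 from 1.58 ± 0.980 to 49.8 ± 1.20. CA9 and ANKRD37 rose by 2.51 and 2.38 on the log2 scale. Of 37 tested targets 34 rose and 0 fell, with a median of 1.97 (camera adjusted p = 5.34e-28, adjusted p = 0.741 with an estimated correlation), and 36 rose adjusted over the list alone. Among the 3 not called were EGLN3 (4.41 ± 0.0460 and 9.99 ± 4.30 normalized TPM, adjusted p = 0.064) and EPAS1 (89.3 ± 6.80 and 138 ± 28.6, adjusted p = 0.0539). EPAS1 was named here after its values were seen. With the number series as a covariate EGLN3 was called (adjusted p = 0.0336).

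Glycolysis genes rose in 16 of 20 cases and none fell, with a median of 1.14 (camera adjusted p = 2.32e-09, adjusted p = 0.741 with an estimated correlation). The hexokinase gene HK2, not to be confused with the cell line, rose by 2.59, ENO2 by 2.54, the glucose transporter gene SLC2A1 by 2.26 and HK1 by 1.24 on the log2 scale. GAPDH, a glycolytic enzyme gene singled out after its values were seen, took 5.32% and 4.54% of the signal in the FG4592 libraries, against 0.873% and 0.652% with DMSO.

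Mitochondrial transcripts fell in 9 of 13 cases, with a median of -1.44 (camera adjusted p = 3.47e-06, adjusted p = 0.741 with an estimated correlation). MT-CYB, cytochrome b, went from 3155 ± 52.4 to 456 ± 243 normalized TPM, and MT-CO3, MT-ND3 and MT-ND2 had log2 fold changes of -2.65, -2.38 and -2.25. The mitochondrial share was 9.88% and 9.35% with DMSO and 2.87% and 4.87% with FG4592. Among 33 nuclear-coded subunits 5 fell and 0 rose (camera adjusted p = 0.0926).

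**Figure D2:**
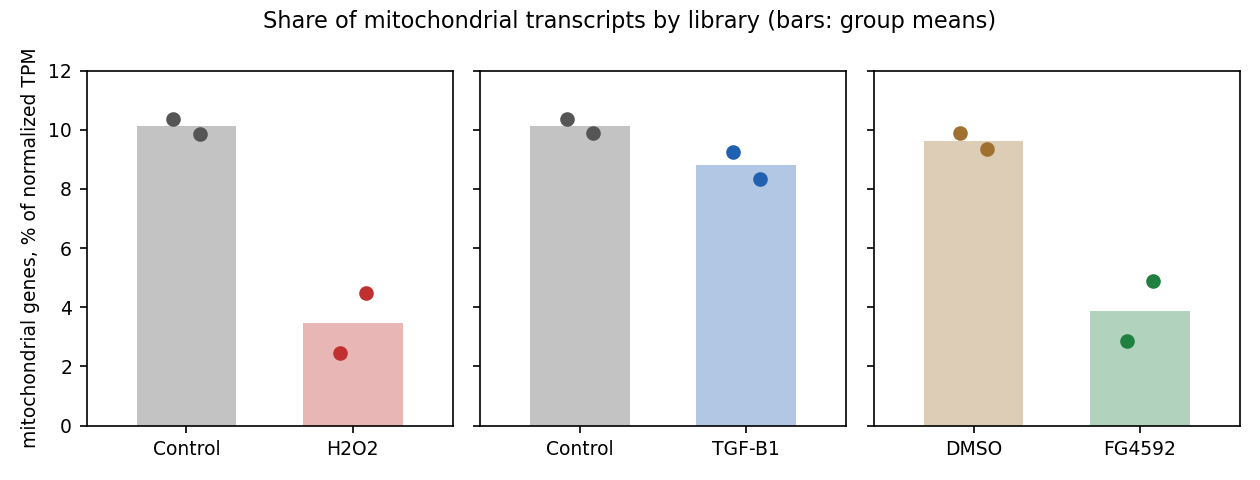
Share of mitochondrially encoded genes in the normalized TPM of each library (percent), with 1 dot per library and bars at the group means. The share lies between 2.45% and 4.87% in the H2O2 and FG4592 libraries and at 8.35% or more in all others.

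Heat shock genes fell in 13 of 21 cases and 0 rose, with a median of -1.06 (camera adjusted p = 3.47e-06, adjusted p = 0.741 with an estimated correlation). HSPA1A, an inducible HSP70 gene that shares reads with HSPA1B, went from 163 ± 50.3 to 22.8 ± 5.64 normalized TPM, and HSPH1 and DNAJA1 had log2 fold changes of -1.71 and -1.67. Replication genes had 7 of 36 members lower, PCNA, MCM6 and MCM4 among them, and 2 higher, CDT1 being 1 of these (camera adjusted p = 0.000513, adjusted p = 0.774 with an estimated correlation). Mitotic genes had 3 of 34 lower, KIF20A, AURKA and CENPA, and 0 higher (camera adjusted p = 0.000613, adjusted p = 0.774 with an estimated correlation), and 0 were called adjusted over the list alone. CDKN1A, the cell cycle inhibitor p21, rose from 64.9 ± 0.0966 to 209 ± 2.31 normalized TPM (adjusted p = 0.001).

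Inflammatory NF-kappaB genes had 13 of 25 members higher and 2 lower (camera adjusted p = 8.62e-05, adjusted p = 0.741 with an estimated correlation). CSF2, TNFAIP3 and ICAM1 rose by 2.06, 1.55 and 1.12 on the log2 scale, and TNFAIP2 had a log2 fold change of -1.49. Interferon genes had 7 of 29 lower, with MX1 at -1.26, and 2 higher (camera adjusted p = 0.0205, adjusted p = 0.741 with an estimated correlation). In the AP-1 family 5 of 16 rose, led by MAFF (1.90), FOSL1 (1.87) and JUN (1.45), and 2 fell (camera adjusted p = 0.0355, adjusted p = 0.741 with an estimated correlation). Autophagy and lysosome genes had 7 of 31 higher and 1 lower, with SQSTM1 at 1.28, CTSD at 1.19 and MAP1LC3B at 1.17 (camera adjusted p = 0.0451, adjusted p = 0.741 with an estimated correlation). Cholesterol synthesis had 0 called of 25 and a median of -0.55 (camera adjusted p = 0.0435, adjusted p = 0.774 with an estimated correlation), and ribosomal protein genes had 0 called of 50, on the higher side (camera adjusted p = 0.00115, adjusted p = 0.774 with an estimated correlation). With the number series as a covariate 17 cholesterol synthesis genes were called lower and 1 higher, and 13 ribosomal protein genes higher. HMOX1 rose from 21.7 ± 2.35 to 134 ± 28.7 normalized TPM, whereas NQO1 had 142 ± 19.6 and 97.5 ± 6.57 (adjusted p = 0.0556, or 0.0147 with the number series as a covariate).

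Beyond the HIF list the largest rises were in the clock repressor BHLHE41 (log2 fold change 5.03), PLIN2, which coats lipid droplets (4.78), DPYSL4 (4.53), the kisspeptin receptor gene KISS1R (4.38), PRTN3 (4.37) and the BMP antagonist NOG (4.32). PLIN2 went from 56.6 ± 6.39 to 1584 ± 132 normalized TPM (adjusted p = 4.17e-05). Other large falls were in CRISPLD2 (-3.04), the matricellular gene THBS1 (-2.50), NPY1R (-2.45), ZBED2 (-2.32) and CTGF, connective tissue growth factor, which went from 208 ± 54.7 to 40.7 ± 2.20 normalized TPM (log2 fold change -2.30 ± 0.20 SE, adjusted p = 0.0012). COL1A1 went from 30.6 ± 0.572 to 15.0 ± 2.56 normalized TPM (adjusted p = 0.0142), and FN1 had a log2 fold change of 1.03 (adjusted p = 0.0282).

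FG4592 against DMSO gave 2782 called genes of 14129, 1430 higher and 1352 lower, of which 878 rose and 569 fell at least 2-fold. With library sums set equal, 34.9% of calls were higher instead of 51.4%, and the median over all genes moved from -0.07 to -0.20. The count was 846 without FG4592 library 05 (593 higher, 253 lower), 1101 without DMSO library 10 (777 higher, 324 lower) and 4503 with the number series as a covariate (2101 higher, 2402 lower). In the last of these fits 36 HIF targets, 16 glycolysis, 16 NF-kappaB and 6 AP-1 genes were higher, 3 NF-kappaB and 2 AP-1 genes, 13 mitochondrial transcripts, 16 heat shock and 22 mitotic genes lower, 2 replication genes higher and 19 lower, 2 interferon genes higher and 12 lower, 11 autophagy genes higher and 5 lower, and 1 nuclear-coded subunit higher and 11 lower. Of 57 called genes named by rule 44 stayed called with any 1 library left out, and 6 of 12 called lists did. Without FG4592 library 05 AURKA, CDT1, CENPA, COL1A1, CTSA, DTX3L, FN1, IFI6, KIF20A, MCM4, MCM6 and PCNA were not called, nor were the lists of the AP-1 family, mitosis, autophagy, cholesterol synthesis, interferon and ribosomal proteins, and without DMSO library 10 AURKA, CENPA, COL1A1, CTSA, DTX3L, FN1, KIF20A and MX1 were not called, nor were autophagy, cholesterol synthesis and ribosomal proteins. AURKA, CENPA and FN1 were not called without FG4592 library 11 either, nor DTX3L without DMSO library 04.

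**Figure D3:**
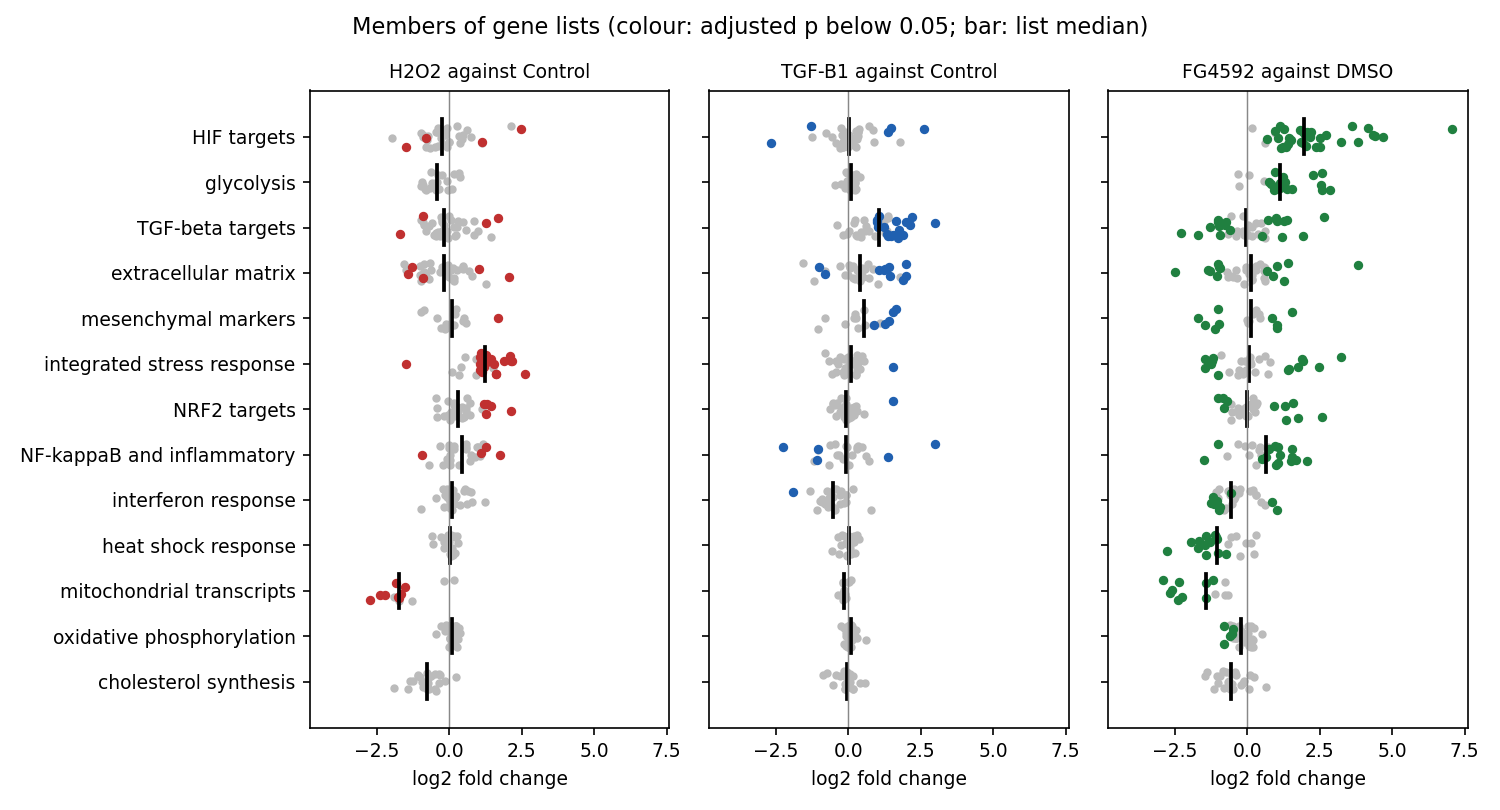
Log2 fold change of every tested member of 13 gene lists with H2O2, TGF-B1 and FG4592, where coloured dots passed an adjusted p of 0.05 and black bars mark list medians. HIF targets have a median of 1.97 with FG4592, TGF-beta targets of 1.05 with TGF-B1 and the integrated stress response of 1.22 with H2O2.

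Set against Control in place of DMSO, FG4592 gave 2492 called genes of 14124, 1284 higher and 1208 lower. HIF targets rose in 35 of 37 cases and glycolysis genes in 16 of 20 (camera adjusted p = 6.13e-31 and 2.39e-11, adjusted p = 0.612 for both with an estimated correlation). Heat shock genes fell in 14 of 21 cases and mitochondrial transcripts in 11 of 13 (camera adjusted p = 2.92e-07 for both, adjusted p = 0.691 for both with an estimated correlation). NF-kappaB genes had 8 of 25 higher and 2 lower (camera adjusted p = 0.00196, adjusted p = 0.612 with an estimated correlation), and AP-1 genes 7 of 16 higher and 1 lower (camera adjusted p = 0.00381, adjusted p = 0.68 with an estimated correlation). Interferon genes had 5 of 29 lower and 0 higher (camera adjusted p = 0.0188, adjusted p = 0.68 with an estimated correlation), and replication genes 5 of 36 lower and 2 higher (camera adjusted p = 0.0205, adjusted p = 0.789 with an estimated correlation). The mitosis, autophagy, cholesterol synthesis and ribosomal protein lists, called against DMSO, were not called against Control in the reported fit (camera adjusted p = 0.0576, 0.0785, 0.0616 and 0.11). ANGPTL4 rose from 1.97 ± 0.836 to 585 ± 85.0 normalized TPM, and HBA1, an alpha globin gene with a near-identical copy, from 2.01 ± 0.559 to 97.2 ± 42.3. HBA1 also stood higher in DMSO than in Control on the common scale (log2 difference 1.621 ± 0.312 SE, limma adjusted p = 0.449). That difference was not called, but part of the rise of HBA1 may not be particular to FG4592. FAM110C (4.58) and ISM2 (4.52) were among the 10 largest rises on the log2 scale, and KCNK2 (-2.76) and LMO4 (-2.43) among the largest falls. COL1A1 had a log2 fold change of -1.45 (adjusted p = 0.0045). FN1 stood at 2438 ± 551 and 3285 ± 180 normalized TPM and did not pass the test against Control (adjusted p = 0.206, or 0.0423 with the number series as a covariate), and EGLN3 at 3.99 ± 0.743 and 9.86 ± 4.23 (adjusted p = 0.0588, or 0.0197). Both FG4592 comparisons shared 1047 higher and 862 lower genes, with 0 in opposite directions, where independent lists would share 132 and 114.2. The FG4592 libraries are the same in both, so the fold changes share chance values. Their correlation was 0.921 and their covariance 0.443, against 0.501 and 0.0299 in simulated unchanged groups, and part of the excess may come from the shared libraries. With library sums set equal, 39.6% of the calls were higher instead of 51.5%, and 1133 genes were called without Control library 07 (761 higher, 372 lower), 1683 without FG4592 library 05 (925 higher, 758 lower) and 3866 with the number series as a covariate (1800 higher, 2066 lower). The last of these fits had 36 HIF targets, 16 glycolysis, 12 NF-kappaB and 7 AP-1 genes higher, 3 NF-kappaB and 2 AP-1 genes and 13 mitochondrial transcripts lower, 1 heat shock gene higher and 16 lower, 2 replication genes higher and 14 lower, and 3 interferon genes higher and 10 lower. Of 50 called genes named by rule 44 stayed called with any 1 library left out, and 6 of 8 called lists did. BST2, DTX3L, GINS4, IFI35, MCM4 and MCM6 were not called without Control library 07, DTX3L not without Control library 01, and GINS4 and IFI35 not without FG4592 library 05. The interferon list was not called without Control library 01, nor replication genes without Control library 07 or FG4592 library 05.

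Open chromatin was compared through the authors' lists of differential regions on hg19, which hold positions only. H2O2 had 11239 regions covering 8.50 Mb, TGF-B1 7875 covering 6.03 Mb, FG4592 against Control 7280 covering 5.34 Mb and FG4592 against DMSO 11853 covering 11.9 Mb. Median widths were 653, 670, 648 and 886 bp. Chromosome 1 held the most regions in each list, from 9.76% to 10.9%. A further deposited list of 4423 FG4592 regions equals the Control-list regions that overlap the DMSO list, but with the runs in the other order. Its run 1 holds 2343 regions of run 2 of the Control list and its run 2 holds 2080 of run 1. Run numbers are therefore not shown to mean the same in every file, and counts by run below compare positions in the files only.

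Run 1 and run 2 of the lists held 4273 and 6966 regions for H2O2, 2654 and 5221 for TGF-B1, 3130 and 4150 for FG4592 against Control, and 7948 and 3905 for FG4592 against DMSO. Of the H2O2 regions 3486 (31.0%) overlapped a TGF-B1 region by at least 1 bp, 3441 of them between regions of the same run number. Both lists use the same Control libraries. FG4592 against Control overlapped 2651 H2O2 regions, 2421 in the same run. FG4592 against DMSO, which shares no library with the H2O2 list, overlapped 2917, with 1447 in the same run and 1470 in the other. Between both FG4592 lists 4416 regions overlapped, 0 of them across runs. In run 1 of the DMSO list the median width was 1102 bp, and 96.4% of the regions on chromosome 19 belonged to that run, against 88.3% in the FG4592-against-Control list and 22.5% in the H2O2 list. Over the 25103 merged regions of all lists, H2O2 and TGF-B1 shared 3488, where random placement within these regions would give 3522.8, a reference that counts listed regions only. The 2 FG4592 lists shared 4412 against 3429.3, and the other 4 pairs shared fewer than this reference, from 1611 against 2278.8 for TGF-B1 with FG4592 against Control to 2913 against 5301.3 for H2O2 with FG4592 against DMSO. Open regions that are in no list are left out, which raises the reference in advance. A count at or below it therefore does not show that lists overlap no more than by chance. Lists with no values per sample allow no test of these overlaps against replicate error.

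**Figure D4:**
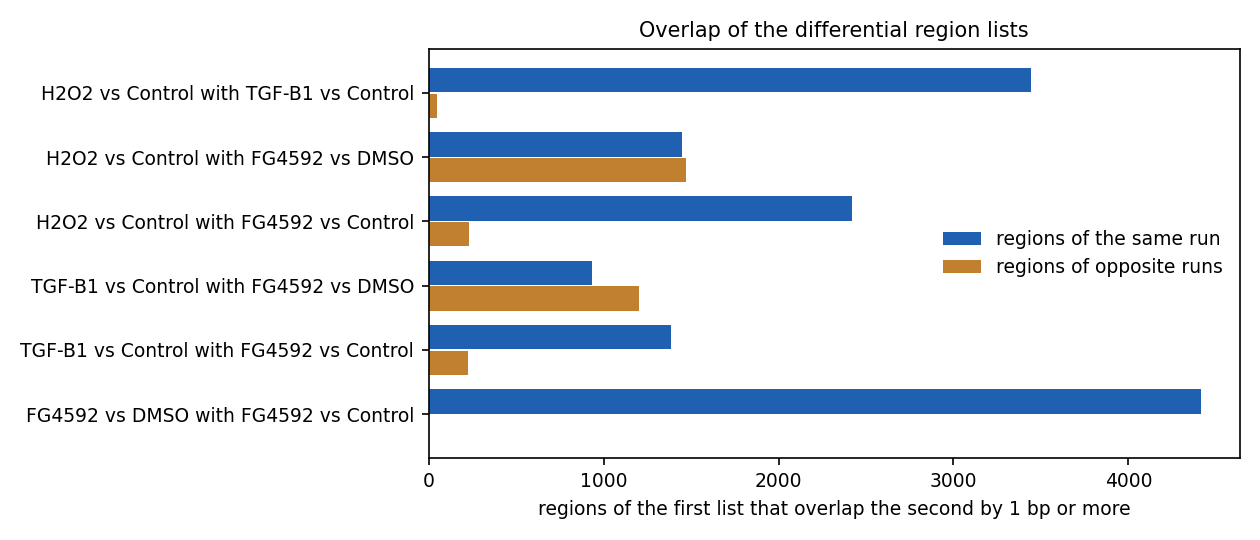
Number of regions of the first list that overlap the second by at least 1 bp, for regions of the same run (blue) and of opposite runs (orange), for the 6 pairs of lists. Overlaps of the H2O2 list lie in the same run in 98.7% of cases with TGF-B1 and in 49.6% with FG4592 against DMSO.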

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

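Chosen after seeing the data were library sums set equal, the number series as a covariate, rows left unsummed and the fit on a common scale. By replicate number, no paired analysis was possible because the library columns carry numbers that the labels do not tie to replicate numbers. The number series of the columns was fitted as a block in its place, which pairs the treated and control libraries of the same series. In each treatment comparison this block left 1 residual degree of freedom, so its p-values lean heavily on variances borrowed from other genes. No simulated shares of called genes are given for it. The reported fits are unpaired, so a gene or list member not called in them may be called with this block. The counts of called genes stayed within 1.5 times of the reported ones with either pseudocount, a filter at 5, a median shift, unsummed rows, equal library sums and the authors' q-values. Without a filter H2O2 gave 85 calls, where more genes were tested. The number series raised the calls to 1181 (H2O2), 1746 (TGF-B1), 4503 (FG4592 against DMSO), 3866 (FG4592 against Control) and 6 (DMSO against Control), and the calls of the reported fits remained, 256, 374, 2782 and 2492. The common scale, whose fit pools the spread of 10 libraries, gave 500 for H2O2 and 594 for TGF-B1. With 1 library left out, the lone library of a group was assumed to vary like the other group. Calls then ranged from 182 to 696 (H2O2), 301 to 373 (TGF-B1), 846 to 2267 (FG4592 against DMSO) and 1133 to 2627 (FG4592 against Control), and called lists for FG4592 against DMSO from 6, without FG4592 library 05, to 16. Where the cause is not named here, the cause was not tested. The authors' deposited tables list 255, 378, 2396 and 2031 genes at q below 0.05, counted over all symbols, of which 137, 249, 1684 and 1482 were also called here. Named genes lay on both sides. Among those called here with H2O2, the authors' q was 0.117 for SLC7A5, 0.129 for GARS, 0.256 for ANGPTL4 and 0.13 for MT-CO2. It was 1.6e-05 for ASNS, 2.6e-05 for NQO1 and 0.0178 for MT-CO1. VEGFA, not called here with H2O2, had 0.00037. With TGF-B1 it was 0.309 for EPCAM and 0.369 for WFDC2, against 1.6e-07 for IL11 and 0.00655 for COL1A1.

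Over named genes and lists, 3604 of 3915 values kept their direction and side of the threshold, 157 lost the call, 141 gained it and 13 changed sign. All sign changes were in genes that were not called. The filter settings and the number series leave a gene's fold change as it is, so only its call could differ there. Calls also ended for NT5E, SPNS2 and TNFAIP3 with H2O2 at a pseudocount of 0.1, TNFAIP3 at 5, and MT1F, NT5E and TNFAIP3 with a median shift, for FN1, MGST1, PRDX1 and WFDC2 with TGF-B1 without a filter, WFDC2 also with a median shift or a pseudocount of 0.1, and for AURKA and FN1 without a filter and AURKA and KIF20A on the common scale with FG4592 against DMSO. With a filter at 5 the lists of the AP-1 family and extracellular matrix (H2O2), apoptosis and p53 targets (TGF-B1), autophagy (FG4592 against DMSO) and interferon (both FG4592 comparisons) were not called, without a filter extracellular matrix (H2O2) and proximal tubule markers (TGF-B1), and with equal library sums ribosomal proteins (TGF-B1), autophagy and cholesterol synthesis (FG4592 against DMSO). On the common scale the AP-1 family (H2O2), ribosomal proteins (TGF-B1) and cholesterol synthesis (FG4592 against DMSO) were not called. The number series ended no list call and added mitochondrial transcripts (TGF-B1) and mitosis, cholesterol synthesis and ribosomal proteins (FG4592 against Control). With equal library sums ANKRD37 with H2O2 moved to 0.006 (log2). On the common scale TXNRD1 with FG4592 against DMSO stood at 0.048. With 1 library left out, log2 fold changes ran from -0.259 to 0.091 for ANKRD37 with H2O2, and with TGF-B1 from -0.65 to 0.78 for CA9, -0.228 to 0.566 for LUM, -0.282 to 0.153 for NQO1 and -0.627 to 0.026 for HMOX1. They ran from -0.17 to 0.932 for SMAD7 and -0.136 to 0.069 for TXNRD1 with FG4592 against DMSO, and from -0.113 to 0.99 for SMAD7 against Control. Overlaps of regions changed little with the stricter and the wider rule, for H2O2 with TGF-B1 from 3486 to 3485 and 3561, and all regions lay on assembled chromosomes. Not run were a stricter score, which the region lists do not hold, and a median shift, equal library sums and unsummed rows for DMSO against Control. The authors' values for lists and DMSO against Control and unsummed rows for named genes and lists were not run either. Alternatives for the differences between treatments and all settings for gene neighbourhoods and motifs were also left out. The authors' q-values of named genes were not counted among the values above. Depth is unknown, so what it limits cannot be stated.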

Other observations

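Tests of explanations in this part were chosen after the results were seen, except that of depth between the number series. Differences between treatments and DMSO against Control were planned tests, on a common scale that was chosen after the data were seen. Genes named only here were chosen after their values were seen.

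Across the 3 treatments, 32 genes were called in each, 4 higher in all, 21 lower in all and 7 in mixed directions. Independent lists would give 0.13 and 0.18 of 13564 genes for the first 2 kinds, although H2O2 and TGF-B1 share their Control libraries and part of the excess may come from them. Fold changes of these 2 had a correlation of 0.388 and a covariance of 0.0794, against 0.501 and 0.0279 in simulated unchanged groups. Higher in all were ANGPTL4, GFPT2, SEMA7A and the protease inhibitor TFPI2, which went from 112 ± 9.14 to 296 ± 132 normalized TPM with FG4592. Lower in all were HAVCR1, ELF3, FGFR2, MMP7, the complement regulator CFI and the defensin DEFB1, with HAVCR1 at log2 fold changes of -2.30 with H2O2, -1.76 with TGF-B1 and -1.08 with FG4592. GDF15 rose with H2O2 (2.29) and FG4592 (1.92) and fell with TGF-B1 (-2.31), and IGFBP3 fell with H2O2 (-1.17) and rose with TGF-B1 (0.72) and FG4592 (1.26).

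On the common scale the difference between H2O2 and TGF-B1 was called for 1007 of 13904 genes. GDF15 differed by 4.60 ± 0.42 (log2, SE, adjusted p = 0.000737), EPAS1 by 3.04 ± 0.25, AREG by 3.08 ± 0.45 and EREG by 3.24 ± 0.63, higher with H2O2, and COL1A1 by -2.90 ± 0.24. In this difference NRF2 targets (median 0.418) and interferon genes (0.668) passed camera, also with an estimated correlation (adjusted p = 0.0399 for each). Against Control, interferon genes had a median of 0.08 with H2O2 (camera adjusted p = 0.232) and -0.52 with TGF-B1. Their difference thus lies mostly in lower values with TGF-B1. For FG4592 over DMSO set against H2O2 and TGF-B1, the lowest adjusted p with an estimated correlation was 0.236 and 0.253. The effect of FG4592 over DMSO differed from that of H2O2 for 1379 genes and from that of TGF-B1 for 1761, with PLIN2 at 4.71 and 5.97 and HILPDA at 4.65 and 4.51. DMSO against Control gave 0 called genes of 13904 with limma and 710 at an unadjusted p below 0.05, about as many as that threshold gives without any change. With the number series as a covariate 6 were called. At the preset correlation camera still called 10 of 29 lists, so list calls also arise in a comparison with 0 called genes. Among them were extracellular matrix (median -0.21, adjusted p = 1.03e-05), ribosomal proteins (-0.16, adjusted p = 2.29e-05), epithelial markers (-0.18, adjusted p = 0.000339) and mesenchymal markers (-0.21, adjusted p = 0.00046) on the lower side in DMSO. HIF targets (0.19, adjusted p = 0.000892), mitotic genes (0.14, adjusted p = 0.00805) and replication genes (0.15, adjusted p = 0.0219) were on the higher side. None of the 10 lists held with an estimated correlation, where the lowest adjusted p was 0.113. KRT7 (log2 difference -1.24 ± 0.14 SE, adjusted p = 0.0823), F3 (-1.34) and IL7R (-1.42) had the smallest p among genes at a mean of 5 or more. EGR1 (3.363 ± 0.598 SE, adjusted p = 0.391) and FOS (2.672 ± 0.555 SE, adjusted p = 0.503) were among those higher in DMSO with the smallest p.

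Mitochondrial transcripts were lower with H2O2 and FG4592. The list median was at most -1.35 over 4 scalings with H2O2 and with FG4592 against DMSO, and at most -1.21 with FG4592 against Control. The choice among these scalings does not account for the fall. They differ little, with log2 factors from -0.195 to 0.1303 on the common scale, so this check could hardly have come out otherwise. All 4 are relative to the signal of the library, and amounts per cell were not tested. Nuclear copies of mitochondrial genes gained at most 6.5% of the share that mitochondrial genes lost. The share was lower in 4 of 4 treated libraries than in the control library of the same number series. It was also lower in both TGF-B1 libraries (9.24% against 10.35% and 8.35% against 9.87%), where the list was not called. The direction alone therefore does not set H2O2 and FG4592 apart. For H2O2 a fall of respiratory chain genes as a whole is argued against by the nuclear-coded list, whose lower quartile was 0.018. For FG4592 a fall as large as that of the mitochondrial transcripts is argued against, because the lower quartile of the nuclear-coded list was at lowest -0.635 over 4 scalings and lay above the upper quartile of the mitochondrial list in each. A smaller fall cannot be told apart, since that quartile was -0.50 as deposited and members went both ways. Fewer mitochondrial genomes, less transcription or faster decay of these RNAs stay open as untested hypotheses.

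Libraries 07 to 12 differed from libraries 01 to 06 in a similar way in every condition. Across genes, the 10 correlations between the conditions' series differences ran from 0.272 to 0.561, and genes are not independent replicates. A shared difference in handling between the series cannot be told apart from other causes, since the correlations, with 0.272 as the lowest, are the pattern itself. Lower depth of 1 series is argued against as the whole cause, because the median correlation was 0.47 among genes at a mean of 50 or more. No biological explanation was tested, and the labels do not say what the numbers stand for.

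Run 1 of the FG4592-against-DMSO region list overlapped mostly run 2 of the H2O2 list. Run numbers are not shown to mean the same in every file, since 1 deposited FG4592 file holds its runs in the other order, although 0 of 4416 overlaps between both FG4592 lists and 45 of 3486 between H2O2 and TGF-B1 were across runs. Width alone is argued against as the cause, since among regions no wider than 657 bp 50.5% of run 1 overlaps were with run 1, although the share was lower, 16.1%, among wider ones. Run 1 regions not shared with the FG4592-against-Control list had 9.3% of their overlaps with run 1 of the H2O2 list and shared ones 61.3%. Shared regions lie in the same run of the Control list, which uses the Control libraries of the H2O2 list and overlaps it in the same run in 91.3% of cases, so this split decides nothing. A difference between the DMSO and Control ATAC-seq libraries, by the solvent or by library quality, cannot be told apart here, since no signal per library was analysed.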
